A study of Homo sapiens and Homo sapiens
Mus musculus and Mus musculus with 9 samples.

How the data were processed

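The samples were single-cell 3' mRNA libraries made by freeze-thaw lysis in microwell arrays (scFTD-seq), in which each well holds a cell and a bead whose primers carry a barcode. After capture the RNA was copied, amplified and tagmented with Nextera XT reagents. The series lists 9 samples, and tables of 6 of them were used here. These are a mix of HEK293, HUVEC and K562 cells, a mouse tumour titled melanoma, and 4 libraries from human blood, which combine 2 cell populations (titled Tcm and cTfh) with 2 treatments (untreated or PMA/ionomycin). The 3 libraries that mix mouse NIH3T3 and human K562 cells were not analysed here.

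The deposited tables hold counts, as whole numbers per gene and 12-base barcode, and no normalization had been applied to them. They were read as UMI counts (counts of distinct molecules), although no header states that reads were collapsed to molecules. The submitters' processing notes name genome builds hg19 and mm10. The aligner, the gene annotation and the rule by which barcodes were chosen for the tables are not given in the sources used here. Every value was checked to be a whole number of 0 or more. Genes with mouse-style symbols were left out of the mix of human cells. Genes are named by the symbols in the tables, and no coordinates were used.

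Barcodes with at least 200 detected genes were kept as cells. No upper limit, no limit on mitochondrial counts and no doublet removal were applied in the main values. Scrublet (as implemented in scanpy) was run per library, and leaving out its calls was an alternative. It called 0 of 1256 cells in stimulated cTfh and 1 of 4990 cells in the cell mix, so it was not informative for these 2 libraries.

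Each group has 1 library, so there are no replicates and no test, p-value or standard error was made. Counts were summed over the cells of a library and given as CPM, counts scaled to a common library total, with exact Poisson intervals. Ratios carry exact conditional binomial intervals and shares of cells carry exact Clopper-Pearson intervals, all at 95%. Intervals and limits cover counting error only, and not the spread between donors, sorts or libraries. Intervals of CPM and of ratios treat each UMI as independent, so they also leave out the spread between cells and are too narrow where cells differ. Where a count was 0, a floor of 3 counts gave the fold stated as "at least" or the upper limit of a share. Such folds leave out the counting error of the other library, so they are not bounds at 95%. Log2 ratios of genes and lists raised counts under 3 to that floor. Shares of cells were computed on the counts as deposited and again with every cell thinned to 1200 UMIs, the lowest of the 4 median UMI numbers rounded down. Cells below that number were left out of the thinned shares. The thinned shares are the main values.

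The 4 comparisons of T cell libraries were stimulated against untreated within each population, and cTfh against Tcm within each treatment. The difference between the stimulation ratios of the populations was described per gene and per list. Named genes were chosen by size: among genes at 50 CPM or more in at least 1 library of a comparison, the 10 highest and the 10 lowest CPM ratios. For each gene list the rule was to name 2 to 4 members, those with the largest ratios first, but the text did not always follow it. Among the feedback genes in Tcm, for example, SPRY1 (log2 ratio 6.84) was passed over for DUSP5 (6.16) and DUSP2 (5.375). Genes that could bear on donor identity, receptor gene segments and clone names were left out. List members were measured where the libraries of a comparison held at least 10 counts together, and a list was summarised by its median log2 ratio and by the members at least 2-fold apart. The percentile of each median was taken among 10000 random lists of equal size matched on mean CPM.

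Cells of the mix and of the tumour were scaled to 10000 counts, transformed as ln(x+1), reduced to 2000 variable genes and 20 principal components, and clustered by the Leiden method at resolution 0.5 on 15 neighbours with seed 0. A cluster was named from fixed marker genes where at least 3 markers, and at least 0.5 of those detected, had 0.5 or more of their highest cluster CPM and UMIs in 5% of its cells. Leading genes of a cluster had at least 100 CPM and UMIs in 25% of its cells, and were ranked by fold over the other cells of the library. The comparisons, gene lists, markers, named-gene rule, clustering settings and alternatives other than 3 were chosen before the data were examined. The scoring rule for cluster names was set after the clusters were seen, and its selection step was corrected once. Those 3 alternatives were chosen after the data were seen: totals without mitochondrial counts, cells with 1000 to 3000 UMIs, and each gene without its highest barcode. Chemokines were made a main value of the stimulated comparison and of the difference after their values were seen.

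Alternatives chosen before the data were examined were every barcode, cells with at least 500 genes, cells under 10% mitochondrial UMIs, Scrublet calls left out, median-of-ratios size factors, the mean of per-cell CPM, thinned cells, list members with at least 50 counts, shares from at least 2 UMIs, Leiden resolutions 0.2 and 1.0, 1000 variable genes and 10 components. The pipeline was tested on simulated data with 200 changed genes: 96.4% and 96.3% of the ratio intervals covered the true ratio in the Tcm and cTfh layouts, and the clustering returned 3 of 3 simulated profiles. The simulated counts were Poisson draws, the model behind the intervals, without spread between cells, and the simulated profiles were set far apart. These tests therefore check the code, and not how well the intervals or classes hold for the real cells. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.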

Results

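Single-cell mRNA counts were obtained from 6 libraries: a mix of human cell lines, a mouse tumour, and 4 libraries of cells from human blood. The blood libraries carry the titles Tcm and cTfh, abbreviations that the labels do not spell out and that in T cell biology usually stand for central memory and circulating follicular helper T cells. No gate, marker or donor is given for them, and each population has 1 untreated library and 1 library treated with PMA/ionomycin, a phorbol ester and a calcium ionophore that together activate T cells. There are no replicates, so every interval covers counting error only. Intervals of CPM and of ratios leave out the spread between cells as well.

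Depth differed between the libraries. Tables of the T cell libraries held 5000 barcodes each, with total counts of 2473298 in untreated Tcm, 1974916 in stimulated Tcm, 1955372 in untreated cTfh and 2371735 in stimulated cTfh. Cells with at least 200 genes numbered 1482, 796, 1218 and 1256 in that order, and they held 90.4%, 83.5%, 86.9% and 89.97% of the counts. Their median UMI numbers were 1369.5, 1917.5, 1250.5 and 1535.5, and mitochondrial genes took 13.8%, 11.4%, 15.8% and 11.1% of their counts. In the cell mix 4990 of 5000 barcodes were kept, with a total count of 10224784 and a median of 1583.5 UMIs and 802 genes per cell. The tumour table gave 574 cells from 575 barcodes, a total count of 2679331 and a median of 3414.5 UMIs per cell. Kept cells of the T cell libraries had medians of 454, 630.5, 446 and 572 genes.

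Stimulated Tcm cells were compared with untreated Tcm cells to describe the response to PMA/ionomycin. IL2, the T cell growth factor, made up 22940 CPM after stimulation and 1.34 CPM (3 counts) in untreated cells, a ratio of 17110 (95% interval 5853 to 82950). The interferon gamma gene IFNG stood at 611 and 0.447 CPM, and TNF at 1331 and 8.05 CPM, 165-fold higher (104 to 280). CD40LG, the ligand by which helper T cells engage B cells, was 151-fold higher (120 to 193) and the early activation receptor CD69 86.6-fold higher (71.7 to 106). Among genes that were lower, KLF2 and S1PR1, which keep resting T cells in circulation, were 16.6-fold (8.86 to 35.1) and 14.2-fold (8.63 to 25.2) lower.

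Cytokine genes had a median log2 ratio of 4.73 in Tcm, with 14 of 16 measured members at least 2-fold higher and 1 at least 2-fold lower. Among the alternatives this median ran from 3.90 without the highest barcode of each gene to 6.11 for members with at least 50 counts. CSF2 was at least 358-fold higher, IL10 at least 81.8-fold higher and TNFSF14 248-fold higher (106 to 766). All 3 measured chemokines were higher, with a median of 6.24. IL8, a neutrophil attractant, stood at 1329 against 0.447 CPM, and CCL20 at 1719 against 22.8 CPM. Immediate early transcription factors had a median of 5.13, and 17 of 19 were at least 2-fold higher. NR4A1, NR4A3 and EGR2 reached 644, 612 and 383 CPM from 1 to 3 counts each in untreated cells. Activation receptors and ligands had a median of 3.26 (13 of 14 at least 2-fold higher), and negative feedback phosphatases and ubiquitin ligases 2.06 (12 of 18). The feedback inhibitors DUSP5 and DUSP2 were 71.5-fold and 41.5-fold higher. For NF-kB pathway genes the median was 1.28, with BCL2A1 170-fold and NFKBID 165-fold higher while 3 of 18 were at least 2-fold lower. MIR155HG, the host transcript of microRNA-155, was 594-fold higher (273 to 1621), and GEM, a small GTP-binding protein, at least 388-fold higher.

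Lists of T helper subsets were also mostly higher in stimulated Tcm. Their medians were 2.98 for Tfh genes (9 of 13 at least 2-fold higher), 3.02 for Th17 genes (6 of 9), 2.51 for Th1 genes (5 of 5), 2.67 for Th2 genes (3 of 4; -0.073 under 10% mitochondrial UMIs) and 3.25 for regulatory T cell genes (7 of 9). CD200 was 86.9-fold higher (43.8 to 203), ICOS 10.8-fold higher (8.66 to 13.7), AHR 10.2-fold higher (6.90 to 15.6) and CTLA4 45.7-fold higher (24.5 to 96.2). Transcription factors of these lists were divided. TBX21 (log2 ratio 2.51) and STAT4 (1.81) were among the higher, and MAF (-1.91), GATA3 (-0.99) and FOXP3 (-0.27) among the lower. In all comparisons these lists share members with the cytokine, chemokine and activation lists, such as IFNG, IL4, IL13, CCL20 and IL2RA. Their medians therefore do not show that subset programmes were induced. Most counts of IL17A (78 of 111) and IL13 (20 of 31) came from a single barcode. The cytotoxic list had 3 measured members and a median of 0.02. Ribosome biogenesis genes had a median of 1.52 (15 of 19 at least 2-fold higher), heat shock genes 1.15 (6 of 11, with 4 of 11 lower) and glycolysis genes 0.76 (7 of 16, with 4 of 16 lower). NOLC1, a nucleolar protein, was 8.19-fold higher, the chaperone HSP90AB1 4.85-fold higher and the glycolytic enzyme PGAM1 11.02-fold higher.

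Other lists were lower or divided in Tcm. Mitochondrially encoded genes had a median of -0.96 (5 of 12 at least 2-fold lower), proliferation genes -1.29 (3 of 4), naive and central memory genes -0.61 (6 of 15), interferon response genes -0.37 (6 of 18) and cytoplasmic ribosomal proteins -0.43 with 0 of 20 beyond 2-fold. Another 4 of 15 naive and central memory and 2 of 18 interferon response genes were at least 2-fold higher. Within these lists BACH2 was 11.96-fold higher, CCR7 3.57-fold lower, GBP2 9.17-fold higher and IFIT2 10.8-fold lower. For cholesterol synthesis the median was -0.12, with INSIG1 12.3-fold and HMGCS1 9.37-fold higher and 5 of 14 members at least 2-fold lower. The T cell receptor complex had a median of -0.06, with CD3G 6.12-fold and LCK 6.09-fold lower and TRBC2 1.67-fold higher. The medians of these last 2 lists became positive with size factors. Genes with the lowest ratios included CDK5R1, 155-fold lower (27.5 to 6146), and members of the GIMAP family of lymphocyte GTPases: GIMAP7 at 18.8 against 888 CPM, 47.3-fold lower (33.2 to 69.8), GIMAP4 20.2-fold lower and GIMAP1 at least 35.9-fold lower. IL16, GCHFR, C16orf54, SUSD3 and CCDC167 were 95.9-, 50.9-, 30.4-, 18.7- and 18.6-fold lower. GLCE was 132-fold lower, but 348 of its 358 counts in untreated cells came from 1 barcode.

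Stimulated cTfh cells were compared with untreated cTfh cells in the same way. IL2 stood at 29790 against 1.18 CPM (2 counts), a ratio of 25300 (7002 to 208900), and IFNG at 6378 against 3.53 CPM, 1805-fold higher (829 to 4920). Chemokines that attract lymphocytes and other leukocytes followed: CCL4 was 843-fold higher (288 to 4090), XCL2 666-fold (119 to 26350) and XCL1 560-fold (100.2 to 22160). IL21, the cytokine by which follicular helper cells act on B cells, was at least 83.6-fold higher. CD40LG was 156-fold (114 to 221) and CD69 63.9-fold (53.0 to 77.7) higher.

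Cytokines had a median log2 ratio of 5.12 in cTfh (16 of 18 at least 2-fold higher) and chemokines 7.11 (9 of 10). Among the alternatives the cytokine median ran from 3.76 under 10% mitochondrial UMIs to 5.435 for members with at least 50 counts. CSF2 was at least 174-fold higher, IL10 123-fold (47.8 to 453), TNF 90.3-fold (57.0 to 153), IL8 at least 160.0-fold and CCL20 119-fold (73.2 to 209). Immediate early factors had a median of 3.67 (16 of 19), activation receptors and ligands 2.87 (13 of 16) and feedback genes 2.11 (14 of 19). NR4A1 was 1088-fold higher (195 to 43010), EGR2 at least 228-fold, TNFRSF9 96.3-fold (26.4 to 799.8) and CRTAM, a receptor of cytotoxic lymphocytes, 58.0-fold (29.2 to 135). The NF-kB list had a median of 1.09 (11 of 19), with NFKBID 356-fold and BCL2A1 102.9-fold higher. MIR155HG and GEM were 582-fold and 505-fold higher.

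The T helper lists again had positive medians: 4.01 for Th2 genes (3 of 4 at least 2-fold higher), 2.65 for regulatory T cell genes (9 of 10), 2.17 for Th17 genes (6 of 9), 1.51 for Tfh genes (10 of 16) and 0.63 for Th1 genes (3 of 8). IL13 and IL4, the cytokines of type 2 responses, were at least 69.0-fold and at least 43.5-fold higher, CTLA4 24.2-fold and CD200 28.6-fold higher, while CXCL13 was 5.65-fold lower (1.86 to 22.97). Ribosome biogenesis genes had a median of 1.28 (16 of 19), glycolysis genes 0.57 (6 of 16), heat shock genes 0.40 (2 of 11) and cholesterol synthesis genes 0.27 (5 of 14). Of the heat shock genes 2 of 11, and of the cholesterol synthesis genes 2 of 14, were at least 2-fold lower. NOP16 was 11.1-fold, PGAM1 12.8-fold and HMGCS1 9.22-fold higher. Cytotoxic genes had a median of 0.35, with GZMK 2.09-fold lower (1.51 to 2.93). Medians were -0.56 for naive and central memory genes (4 of 15 at least 2-fold lower), -0.77 for proliferation genes (2 of 12), -0.33 for mitochondrially encoded genes (1 of 12), -0.25 for cytoplasmic ribosomal proteins (0 of 20), -0.23 for interferon response genes (2 of 18) and 0.01 for the T cell receptor complex (4 of 13), a sign that turned without mitochondrial counts in the total. At least 2-fold higher were 3 of 15 naive and central memory, 2 of 12 proliferation, 3 of 18 interferon response and 1 of 13 T cell receptor genes. Against random lists, several cTfh medians lay within the central 95%. These were mitochondrially encoded (percentile 4.77), ribosomal protein (6.02), proliferation (9.345), interferon response (40.5) and T cell receptor complex genes (48.7). Others were heat shock (77.75), cytotoxic (90.8), cholesterol synthesis (92.2), Th1 (95.5) and glycolysis genes (95.8). KLF2 was 18.6-fold, S1PR1 10.1-fold and CD3G 5.36-fold lower, and GBP2 8.37-fold higher. The lowest ratios belonged to CDK5R1 (at least 64.5-fold lower), S1PR4, a receptor for sphingosine-1-phosphate (35.7-fold), GIMAP7 (20.3-fold), IL16 (18.2-fold), C16orf54 (17.8-fold), GCHFR (14.8-fold), RNF166 (14.8-fold) and ARRDC2 (12.4-fold). SPATA22 was 17.2-fold lower, with 207 of 369 untreated counts in 1 barcode.

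**Figure D1:**
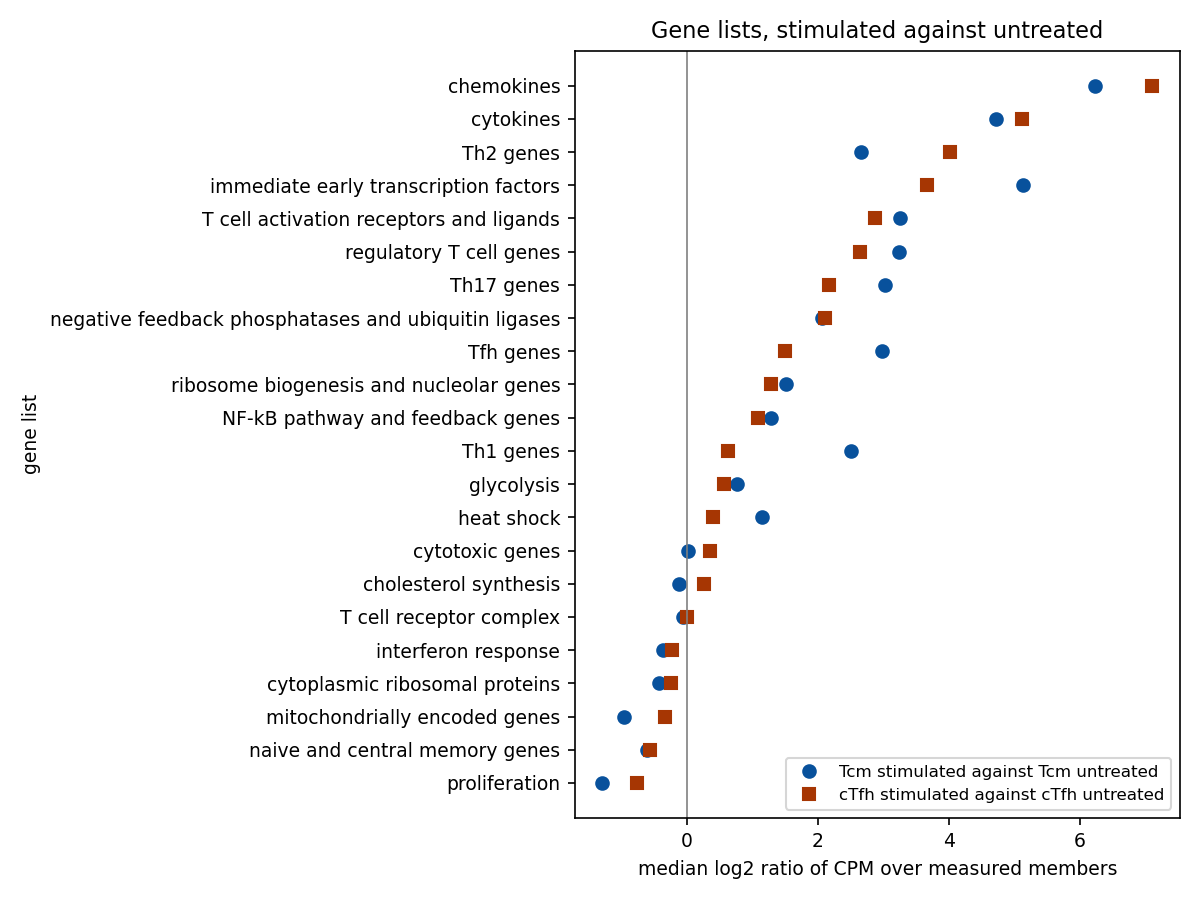
Median log2 ratio of CPM, stimulated over untreated, over the measured members of each gene list, with circles for Tcm and squares for cTfh. Chemokine medians were 6.24 and 7.11 and cytokine medians 4.73 and 5.12, and those of proliferation genes -1.29 and -0.77. These medians cover unlike gene sets: 3 and 10 chemokines, 16 and 18 cytokines, and 4 and 12 proliferation genes. Over the same genes in both populations they were 0.44 and 7.11, 3.755 and 4.75, and 0.44 and -0.74. Of those genes, 8 of 10, 14 of 20 and 7 of 13 had under 3 counts in a library and entered at that floor.

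Both populations responded alike across genes. The log2 ratios had a Pearson r of 0.914 across 2643 genes, which are not independent replicates, and 88.95% of these genes had ratios of the same sign. Against total counts, size factors shifted all log2 ratios by 0.19 and 0.16 for the Tcm and cTfh stimulations, and by -0.14 and -0.18 for cTfh against Tcm in untreated and stimulated cells. Ribosomal, mitochondrial and T cell receptor list medians are to be read against these shifts.

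The stimulation ratios of the populations were compared by the difference of their log2 ratios, cTfh minus Tcm, without a test. Genes with under 3 counts in a library enter these medians at that floor, which bears on most cytokines and chemokines. The chemokine median was 2.88 with 8 of 10 genes at the floor (CCL3, CCL4, XCL1, XCL2 and IL8 among them), and 0.13 for CCL5 and CCL20, the 2 above it. It was 1.197 in thinned cells, 1.76 under 10% mitochondrial UMIs and 6.95 for genes with at least 50 counts. The cytokine median was 0.47 with 14 of 20 genes at the floor and -0.73 for the 6 above it, and it reversed to -0.16 under 10% mitochondrial UMIs. TNFSF14 differed by -2.53 (-3.98 to -1.07), TNF by -0.87 (-1.82 to 0.07), CCL20 by 0.66 (-0.15 to 1.47) and LTB by 0.54 (0.29 to 0.79). IFNG, IL21, IL4, IL22, CCL4 and XCL1 had an untreated count under 3 in at least 1 population, so no difference is given for them. Mitochondrially encoded genes (0.54), cytoplasmic ribosomal proteins (0.14) and ribosome biogenesis genes (-0.15) had 0 genes at the floor. For other lists the median of all measured genes is followed by that of genes above the floor: Tfh genes -0.54 and -0.52, heat shock -0.43 and -0.49, immediate early factors -0.48 and -0.12, activation receptors -0.11 and -0.11, regulatory T cell genes -0.16 and -0.22, glycolysis -0.07 and -0.04, NF-kB genes -0.03 and -0.04, interferon response -0.02 and -0.02, feedback genes 0.10 and 0.10, cholesterol synthesis 0.07 and 0.02, Th1 genes -0.58 and -1.76, and cytotoxic genes -0.22 and -1.59. Medians of Th2 (1.24 and -0.06), Th17 (-0.40 and 0.15) and proliferation genes (0.16 and -0.16) changed sign. Those of naive and central memory genes (0.03) and of the T cell receptor complex (0.01) changed sign with the scaling.

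Untreated cTfh cells were compared with untreated Tcm cells to describe what sets the populations apart at rest. Genes of follicular helper cells were higher in cTfh, with a median log2 ratio of 1.956 and 9 of 14 at least 2-fold higher, and medians of 1.37 under 10% mitochondrial UMIs and 1.24 for members with at least 50 counts. The inhibitory receptors PDCD1 and TIGIT were 22.4-fold (5.74 to 192) and 4.68-fold (3.59 to 6.17) higher, the transcription factors TOX2, TOX and MAF 12.2-fold (5.61 to 31.6), 11.6-fold (4.61 to 37.5) and 3.21-fold (2.61 to 3.98), and the B cell attractant CXCL13 at least 7.90-fold. CXCR5, the homing receptor of follicular helper cells, was 1.47-fold higher (1.10 to 1.95). Granzyme K (GZMK) stood at 58.9 against 0.894 CPM, 65.8-fold higher (17.8 to 551).

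Cytotoxic genes had a median of 2.13 (5 of 7 at least 2-fold higher), with CST7 21.9-fold (9.001 to 69.1) and NKG7 at least 6.15-fold higher. Th1 genes had a median of 2.08 (4 of 5), with EOMES 14.1-fold (4.39 to 71.7) and CXCR3 5.49-fold (2.88 to 11.3) higher. Regulatory T cell genes had a median of 1.57 (5 of 8) and proliferation genes 1.40 (5 of 8). Of 3 measured chemokines, with a median of 2.98, CCL5 was 14.5-fold higher (6.70 to 37.2) and CCL20 2.42-fold lower (1.36 to 4.55). Feedback genes had a median of 0.65 (5 of 15), with DUSP4 11.6-fold and DUSP2 4.75-fold higher. Immediate early factors had 0.51 (4 of 13), with NR4A2 4.74-fold higher (3.02 to 7.71). Activation receptors had 0.44 (4 of 13; -0.012 for members with at least 50 counts), with HLA-DRA at least 9.66-fold higher. Smaller medians were 0.40 for interferon response (-0.035 under 10% mitochondrial UMIs), 0.28 for heat shock, 0.23 for cytokine, 0.21 for T cell receptor complex, 0.29 for Th2, -0.09 for NF-kB, -0.23 for Th17, -0.28 for mitochondrially encoded and -0.27 for cytoplasmic ribosomal protein genes. Naive and central memory (0.08), glycolysis (0.08), ribosome biogenesis (0.06) and cholesterol synthesis genes (0.03) turned negative with size factors. KLF2 was 1.996-fold higher and IL7R, the interleukin-7 receptor, 1.502-fold lower (1.42 to 1.59).

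Other genes with high ratios in untreated cTfh were MIR4435-1HG, 10.7-fold higher (6.02 to 20.8), and BCL2L11, a mediator of cell death, 3.83-fold higher, with CCDC50, NMB, TUBA4A and RNF19A between 3.75-fold and 3.25-fold. Apart from GLCE, whose Tcm counts came mostly from 1 barcode, the lowest ratios were small. MGAT4A was 2.15-fold lower (1.64 to 2.85), LYRM5 1.93-fold, COMMD1 1.88-fold, ANK3 1.87-fold, USP10 1.83-fold, SH3YL1 1.79-fold and SLK 1.74-fold lower. The log2 ratio of SH3YL1 reversed to 0.12 under 10% mitochondrial UMIs. RPL17 and RPSAP58, 1.92-fold and 1.76-fold lower, have near-identical copies whose reads may not be assigned uniquely.

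Stimulated cTfh cells were compared with stimulated Tcm cells to describe which products set the activated populations apart. CCL4 stood at 1489 CPM in cTfh and at 1 count in Tcm, a ratio of 2456 (440.5 to 97040). XCL2, XCL1 and CCL3 had 0 counts in Tcm and were at least 216-fold, at least 181-fold and at least 162-fold higher in cTfh. IFNG was 10.4-fold higher (9.79 to 11.1), IL21 11.1-fold (7.18 to 17.9) and IL4 10.6-fold (5.89 to 20.9). IL8 was 4.70-fold lower in cTfh (4.30 to 5.15), CCL20 1.53-fold lower (1.45 to 1.62), and IL22, an epithelial-acting cytokine, 23.8-fold lower (11.2 to 60.5) on 129 Tcm counts in 6 cells.

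Chemokines had a median of 3.50 in this comparison (7 of 9 at least 2-fold higher in cTfh, 1 lower) and cytokines 0.46 (9 of 19 higher, 2 lower). The chemokine median was 2.77 in thinned cells, 5.12 under 10% mitochondrial UMIs, 5.53 without the highest barcode of each gene and 7.34 for genes with at least 50 counts. CCL5 was 10.9-fold higher (7.72 to 16.0). CCL4L2 and CCL4L1 were at least 38.4-fold and at least 28.1-fold higher, but these copies of CCL4, like XCL1 and XCL2, are so alike that the split of counts between them is uncertain. The cytotoxic list had a median of 2.52 (6 of 7), with GZMK 23.2-fold (6.15 to 196), CST7 5.74-fold (3.86 to 8.85) and NKG7 at least 7.73-fold higher. GZMB was at least 40.7-fold higher, with 109 of 158 counts in 1 barcode. CRTAM was 26.5-fold higher (16.4 to 45.8), with 12 of its 17 counts in stimulated Tcm in 1 barcode, and its log2 ratio went from 4.73 to 6.43 without the highest barcode of each library. ZEB2, a transcription factor of effector lymphocytes, was 23.5-fold (9.85 to 73.4) and TNFSF9 18.6-fold (9.64 to 41.3) higher. Tfh genes had a median of 1.51 (8 of 15), with TOX 9.66-fold, MAF 6.59-fold and TIGIT 3.40-fold higher. Th1 genes had 1.74 (4 of 7), Th2 genes 1.57 (2 of 4), regulatory T cell genes 1.37 (8 of 10), proliferation genes 1.43 (5 of 8), feedback genes 0.79 (7 of 19), activation receptors 0.49 (6 of 16; -0.045 under 10% mitochondrial UMIs) and interferon response genes 0.45 (6 of 17), with IL10 2.64-fold and IFIT2 16.0-fold higher.

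Th17 genes had a median of -0.45 in stimulated cTfh against stimulated Tcm, and 0.026 without the highest barcode of each gene. The remaining medians were 0.26 for the T cell receptor complex, 0.25 for mitochondrially encoded, 0.21 for glycolysis, -0.01 for heat shock, -0.07 for NF-kB, -0.12 for ribosome biogenesis and -0.12 for ribosomal protein genes. Naive and central memory (0.14), cholesterol synthesis (0.10) and immediate early genes (0.08) turned negative with size factors. IER3, an immediate early gene, was 5.16-fold lower (4.15 to 6.48), and YBX3, TIMP1, KLHL21 and TAOK1 were 4.31-, 3.40-, 3.11- and 2.89-fold lower. The small nucleolar RNAs SNORD13 and SNORD89 were 4.44-fold and 2.78-fold lower. SPATA22 was 44.2-fold lower, with 358 of 923 Tcm counts in 1 barcode.

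**Figure D2:**
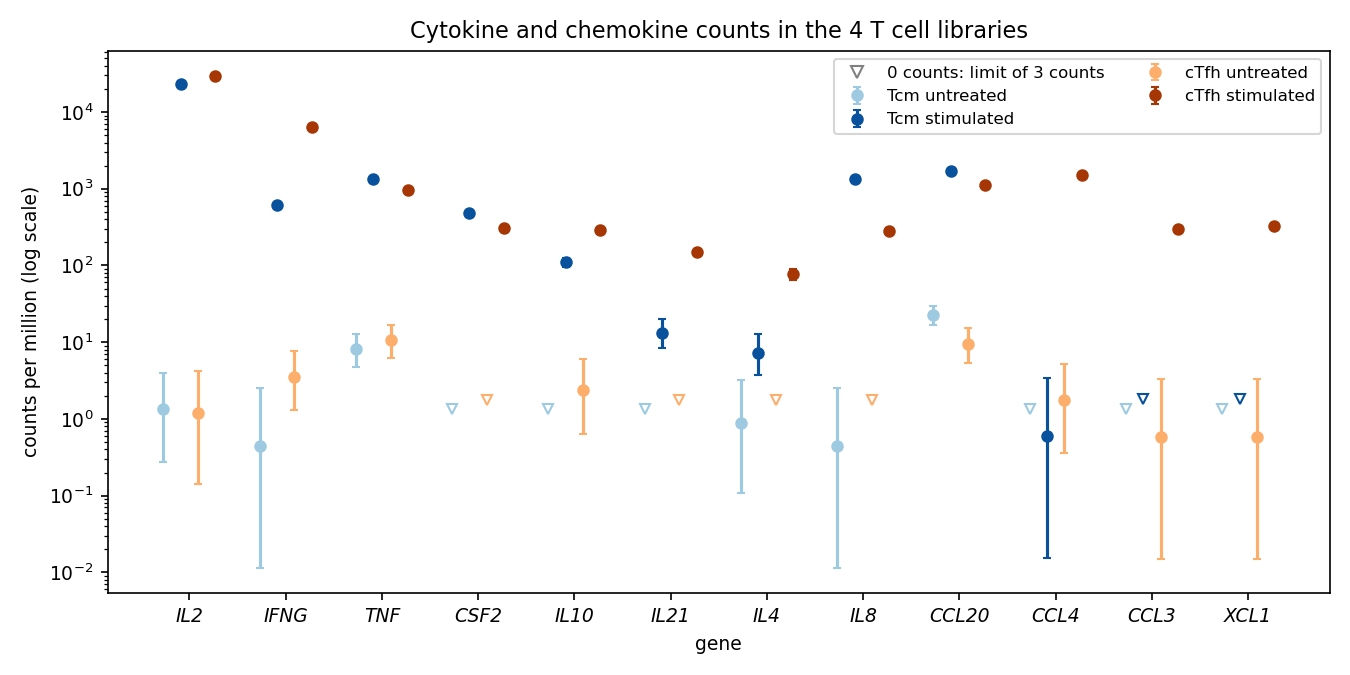
CPM, on a log axis, of cytokine and chemokine genes in each T cell library, with exact Poisson intervals of 95%; open triangles mark the level of 3 counts where the count was 0. IL2 stood at 22940 and 29790 CPM in the stimulated libraries, and CCL4 at 1489 CPM in stimulated cTfh against 0.606 CPM in stimulated Tcm.

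Markers of other blood cells were nearly absent from the T cell libraries. Receptor genes of low level can be missed at this depth, so this does not show that the libraries were pure. CD4 itself had UMIs in 10 of 1256 stimulated cTfh cells. Of the B cell, monocyte, CD8 T cell, NK cell, platelet and red cell lists, CD79B, VCAN and SPON2 alone reached 10 counts in a comparison. SPON2, an NK cell gene, had 21 counts in untreated Tcm and 1 after stimulation, and VCAN, a monocyte gene, 10 and 0.

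Shares of cells with a cytokine UMI were compared after thinning to 1200 UMIs, which left 913 untreated Tcm, 549 stimulated Tcm, 648 untreated cTfh and 793 stimulated cTfh cells and left out 569, 247, 570 and 463. IL2 UMIs were present in 94.9% (92.7 to 96.6) of stimulated Tcm and 94.3% (92.5 to 95.8) of stimulated cTfh cells, and in 0.219% and 0.154% of untreated cells. At least 5 IL2 UMIs were present in 63.2% and 62.2% of the stimulated cells. Barcodes with under 100 genes held IL2 UMIs in 48.1% and 48.4% of cases in these libraries. The source of those UMIs could not be settled, so a single IL2 UMI may not mark an expressing cell. IFNG was found in 12.02% (9.42 to 15.04) of stimulated Tcm and 61.9% (58.4 to 65.3) of stimulated cTfh cells, with at least 5 UMIs in 3.64% and 30.3%. TNF was found in 56.7% and 43.0%, CD40LG in 92.9% and 74.5%, IL8 in 21.7% and 4.79%, CCL20 in 39.7% and 20.8%, CSF2 in 7.65% and 5.30% and IL10 in 7.83% and 11.1% of stimulated Tcm and cTfh cells. IL21 was found in 11.5% (9.34 to 13.9) of stimulated cTfh and 0.911% of stimulated Tcm cells. CCL4 was found in 14.8% (12.4 to 17.4) of stimulated cTfh cells and 0 of 549 stimulated Tcm cells, a limit of 0.546% on detection at this depth and not on the share of cells that express it. GZMK was found in 4.17% of untreated and 2.65% of stimulated cTfh cells. LTB, the lymphotoxin beta gene, was found in 58.6% and 47.2% of untreated Tcm and cTfh cells and in 14.6% and 16.1% after stimulation.

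**Figure D3:**
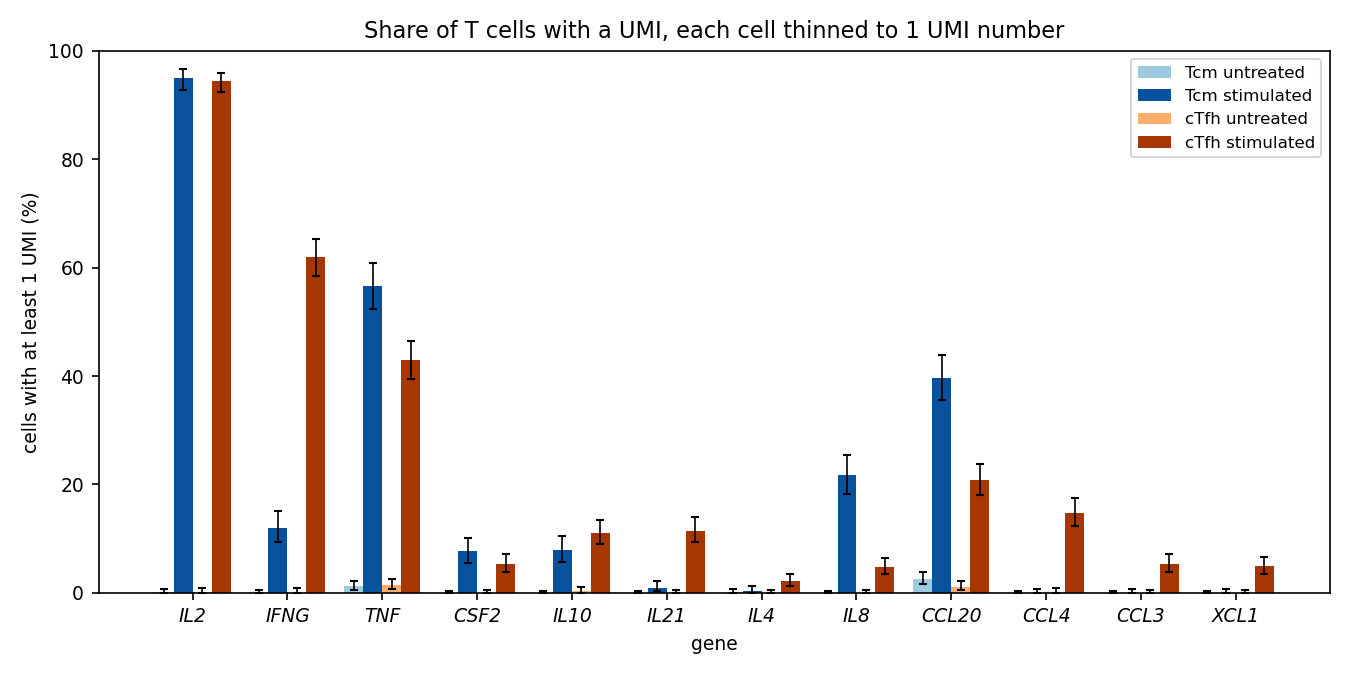
Share of cells, in percent, with at least 1 UMI of each gene after thinning every cell to 1200 UMIs, for the 4 T cell libraries, with Clopper-Pearson intervals of 95%. IFNG was found in 12.02% of stimulated Tcm and 61.9% of stimulated cTfh cells, and IL2 in over 94% of both.

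Without thinning, IL2 was found in 96.4% and 95.1%, IFNG in 17.8% and 69.2%, TNF in 62.6% and 46.3%, CD40LG in 92.6% and 77.4%, IL21 in 2.01% and 12.7% and CCL4 in 0.126% and 21.2% of stimulated Tcm and cTfh cells. Low-count barcodes held IFNG UMIs in 2.58% and 21.5%, TNF in 7.84% and 4.37%, CD40LG in 22.9% and 13.5%, IL8 in 5.95% and 0.476%, CCL20 in 6.57% and 2.94%, IL21 in 0.0797% and 0.803% and CCL4 in 0.0% and 4.58% of cases. In untreated cells the thinned shares were 0.110% and 0.154% for IFNG, 1.21% and 1.39% for TNF and 3.07% and 1.39% for CD40LG. Among cells with at least 1000 UMIs, IL2 had 10th, 50th and 90th percentiles of 1261, 11510 and 64320 CPM in stimulated Tcm and 838, 15590 and 78490 CPM in stimulated cTfh.

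The mix of human cells was clustered to see whether its 3 kinds of cells separate: HEK293, an embryonic kidney line, HUVEC, endothelial cells of the umbilical vein, and K562, an erythroleukaemia line. HUVEC-like cells numbered 2319 (46.5%, 45.1 to 47.9), K562-like cells 1354 (27.1%, 25.9 to 28.4) and HEK293-like cells 1317 (26.4%, 25.2 to 27.6). K562-like cells carried embryonic and fetal globins, with HBG2 at 9134, HBG1 at 5751 and HBE1 at 4010 CPM against at most 24.99 CPM elsewhere. HUVEC-like cells carried CAV1 at 1573, TM4SF1 at 697 and the endothelial receptor gene ECSCR at 591 CPM. HEK293-like cells carried CKB, brain creatine kinase, at 903 CPM and the neurofilament genes NEFL and NEFM at 81.4 and 79.8 CPM.

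HUVEC-like cells fell into cluster 1 (1323 cells, led by MGP and GNG11) and cluster 3 (996 cells, led by THBS1, PTX3 and CTGF). K562-like cells fell into cluster 4 (973 cells) and cluster 5, whose 381 cells had a median of 566 UMIs, were led by the nuclear RNA NEAT1 and had 0 globin genes among their leading genes. HEK293-like cells were led by HEY1, 89-fold over the other cells. Heat shock genes were highest in K562-like cells in 9 of 12 cases, with HSP90AB1 at 5490 CPM against 1768 in HEK293-like and 1195 in HUVEC-like cells and HSPA1A at 162 against 0 and 3.14 CPM. K562-like cells were also highest for 16 of 19 ribosome biogenesis, 13 of 18 proliferation, 10 of 16 cholesterol synthesis and 9 of 17 glycolysis genes. HUVEC-like cells were highest for 7 of 11 interferon response and 7 of 15 NF-kB genes, and HEK293-like cells for 6 of 12 mitochondrially encoded genes. That last list leaves out mitochondrial ribosomal RNA. The median share of all mitochondrial counts was highest in HUVEC-like cells, at 9.28% against 5.655% in HEK293-like and 5.25% in K562-like cells. At least 3 UMIs of markers of more than 1 line were found in 71 cells (1.42%, 1.11 to 1.79), of which 67 were K562-like cells with HEK293-like markers. CKB stood at 275.5 CPM in K562-like cells, so such cells do not count doublets.

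The tumour library was clustered to describe its cells. Of 574 cells, 236 were macrophage or monocyte-like (41.1%, 37.1 to 45.3). Other named classes were neutrophil-like cells (49 cells, 8.54%, 6.38 to 11.1), T or NK cell-like cells (42 cells, 7.32%, 5.32 to 9.76) and fibroblast-like cells (11 cells, 1.92%, 0.960 to 3.40). Macrophage or monocyte-like cells carried the lysozyme gene Lyz2 at 8807 CPM and the complement gene C1qb at 2555 CPM. Neutrophil-like cells carried S100a8 at 4098 and S100a9 at 2963 CPM, T or NK cell-like cells Nkg7 at 1138 and Trbc2 at 725 CPM, and fibroblast-like cells the collagen gene Col3a1 at 8036 CPM. Another 3 clusters stayed unnamed, with 128, 60 and 48 cells (22.3%, 10.5% and 8.36%).

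Genes of antigen presentation by MHC class II were highest in macrophage or monocyte-like cells in 7 of 7 cases, with H2-Ab1 at 2620 CPM. MHC class I genes were highest in T or NK cell-like cells in 5 of 10 cases. Chemokines were highest in neutrophil-like cells in 8 of 14 cases, with Cxcl2, a neutrophil attractant, at 5331 CPM, and interferon response genes in 6 of 14. Extracellular matrix genes were highest in fibroblast-like cells in 9 of 13 cases, with Sparc at 6040 CPM. Of 9 genes of alternative macrophage activation, 4 were highest in macrophage or monocyte-like cells, where arginase 1 (Arg1) stood at 1774 CPM, against 1903 CPM in neutrophil-like cells. The heat shock and immediate early list had no leading class, with 3 of 12 highest in neutrophil-like cells. C1qb also reached 1739 CPM in neutrophil-like and 1002 CPM in T or NK cell-like cells, so the classes are not free of each other's RNA. Class shares depended on the clustering settings: the T or NK cell-like share was 12.2% when the 1 barcode under 200 genes was added and 0.0% at resolution 0.2. Macrophage or monocyte-like cells made up 20.7% and neutrophil-like cells 22.3% of cells with at least 500 genes, and the former 18.8% with 1000 variable genes. The fibroblast-like share was 12.5% with at least 500 genes, 30.3% under 10% mitochondrial UMIs and 39.6% at resolution 0.2.

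Genes of the unnamed clusters set them apart from the immune cells. Spp1, the secreted matrix protein osteopontin, stood at 15430, 25670 and 10870 CPM in unnamed clusters 2, 3 and 5, against 709 CPM in macrophage or monocyte-like cells. Cluster 3, led by Syn3, Timp3 and Enpp2, was highest for 11 of 16 glycolysis and hypoxia genes, with Vegfa at 174 CPM. Cluster 5, led by Pbk and Ube2c, was highest for 13 of 18 proliferation genes, with Top2a at 943 CPM. Cluster 2 was led by Cst6 and the noncoding RNAs Snhg6 and Gas5. Of the melanocyte markers, Mitf had at most 31.1 CPM in any class, Trpm1 at most 2.07 CPM, and the others were not listed in the table. Tables of the T cell libraries differ in gene rows (16884 to 18720), so a gene that is not listed most likely had no counts. Melanocyte markers were thus few or undetected in this library, and no cluster could be named melanoma cell-like.

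**Figure D4:**
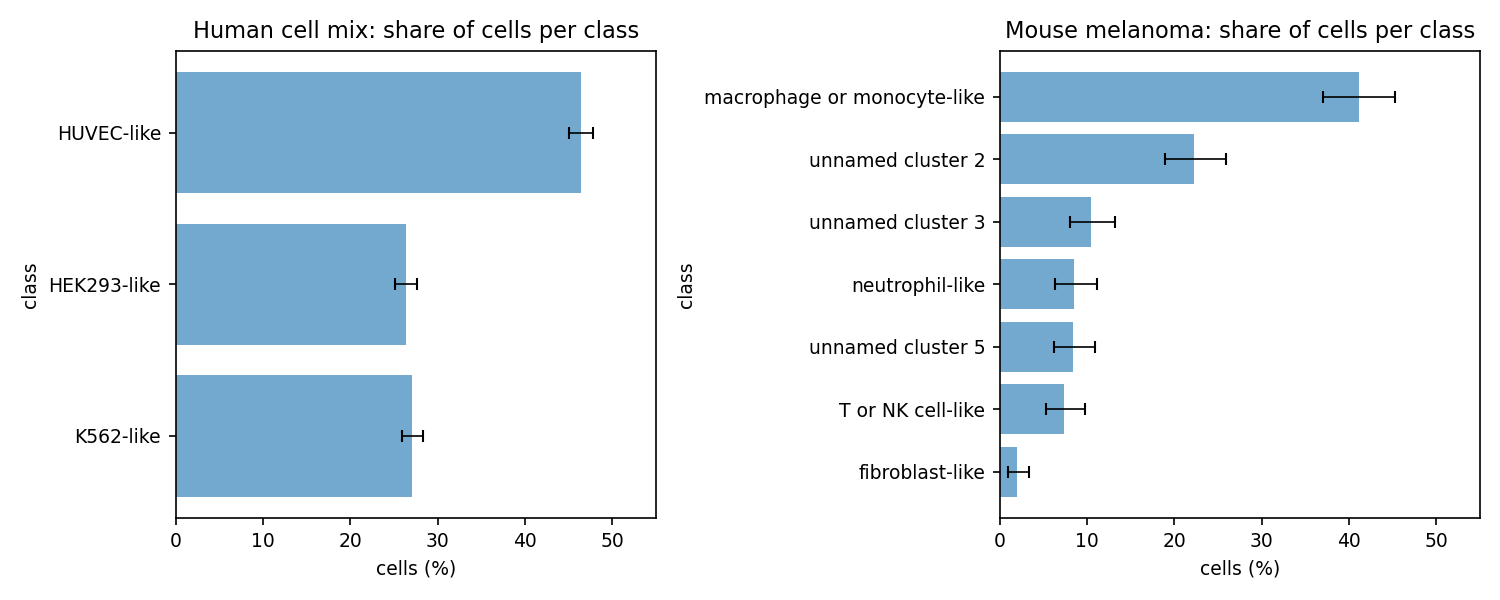
Share of cells, in percent, in each class of the human cell mix (left) and of the mouse melanoma (right), with Clopper-Pearson intervals of 95%. HUVEC-like cells made up 46.5% of the mix and macrophage or monocyte-like cells 41.1% of the tumour cells.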

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

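The test of free RNA against the IL2 counts of cells was chosen after the result was seen.

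IL2 and IFNG, cytokine genes switched on by stimulation, also had UMIs in barcodes with under 100 genes, which enter the comparisons only in the alternative with every barcode. In these barcodes IL2 stood at 17700.0 CPM in the stimulated Tcm and 30300.0 CPM in the stimulated cTfh library, and IFNG at 622 and 7670.0 CPM, close to the levels in cells (22940, 29790, 611 and 6378 CPM). In the untreated libraries IFNG had 0 UMIs in such barcodes, and IL2 had 0 in Tcm and 12 in cTfh, present in 0.0583% of them.

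For IL2 in these barcodes, free RNA shared by all wells and remnants of single cells were weighed, and no biological explanation was tested. The mean number of IL2 UMIs per low-count barcode was 2.25% (Tcm) and 2.76% (cTfh) of the mean per cell, but CD3D gave 2.504% and 2.51% too, since these barcodes are chosen for few genes, so this test cannot decide whether free RNA adds to the IL2 counts of cells. IL2 counts scattered over low-count barcodes with a dispersion of 1.95 and 2.5, where 1 shared pool gave 0.950 to 1.05 and 0.939 to 1.05, and the excess was 49.8% and 71.6% of that of cells thinned to equal totals. CD69 scattered more in low-count barcodes (1.52 and 1.41) than in thinned cells (1.18 and 1.15), so another source of scatter exists, and a shared pool and remnants of single cells cannot be told apart.

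Among list members and named genes, IFIT1, SPATA22 and VCAN had ratios of at least 2-fold in opposite directions in the 2 populations. These differences, with counts under 3 raised to 3, were not tested. Further genes had ratios of opposite sign below that size in 1 or both populations, such as TUBA4A (log2 ratio 1.37 in Tcm and -0.51 in cTfh). IFIT1, an interferon-induced gene, went from 16 counts untreated to 1 stimulated in Tcm and from 4 to 11 in cTfh, a log2 difference of 3.11 (0.68 to 5.53). VCAN, a proteoglycan gene of monocytes, had 10 and 0 counts in Tcm and 3 and 9 in cTfh, a difference of 2.55 with an interval that includes 0 (-0.10 to 5.20). SPATA22, a meiosis gene, had 170 and 923 counts in Tcm and 369 and 27 in cTfh, a difference of -6.98 (-7.59 to -6.37). Single barcodes held 110, 358, 207 and 6 of these SPATA22 counts.

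Mouse-style gene symbols held 5527 counts in the mix of human cells, 0.0541% of its total. Their source was not tested.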

How the results depend on the processing

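Totals without mitochondrial counts, cells with 1000 to 3000 UMIs and genes without their highest barcode were tests chosen after the data were seen. Of the list medians under all alternatives, 1084 stayed within their counting intervals, 198 moved beyond them and 6 reversed. Only values whose interval left out 0 could count as reversed, so sign changes of medians near 0 are among those that stayed or moved. For named genes these numbers were 669, 126 and 5, and for other values 69 stayed and 47 moved. Except where stated, the cause was not tested.

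With every barcode, the cTfh cytokine median was 5.33. Median UMIs were 65 and 68 (Tcm untreated, stimulated) and 62 and 59 (cTfh), since low-count barcodes enter. The melanoma shares were 12.2% T or NK cell-like and 36.2% macrophage or monocyte-like. Cells with at least 500 genes gave cytokine medians of 5.09 (Tcm) and 4.41 (cTfh), a chemokine median of 3.21 between stimulated libraries, and median UMIs of 1960.0, 2477, 1874 and 2047, and 1743 in the mix. Mix shares were 28.5% HEK293-like, 32.0% HUVEC-like, 24.3% K562-like and 15.2% unnamed. Melanoma shares were 14.4% T or NK cell-like, 12.5% fibroblast-like, 20.7% macrophage or monocyte-like, 22.3% neutrophil-like and 30.2% unnamed.

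Under 10% mitochondrial UMIs, the cTfh cytokine median was 3.76 and the difference between populations reversed to -0.16. Chemokines had 5.12 between stimulated libraries and 1.76 for the difference, and Tfh genes 1.37 between untreated libraries. Also reversed were activation receptors between stimulated libraries (-0.045), Th2 genes in Tcm (-0.073), interferon response between untreated libraries (-0.035), GLCE (0.12 in Tcm, 1.19 between untreated libraries) and SH3YL1 (0.12). IL2 was found in 96.5% of stimulated cTfh and IFNG in 15.1% of stimulated Tcm cells. Median UMIs were 1313, 1334.5, 928 and 1258, and 1633 in the mix. Shares were 32.2% HEK293-like, 37.5% HUVEC-like and 30.3% K562-like in the mix, and 30.3% fibroblast-like and 8.37% unnamed in the tumour.

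Size factors gave cytokine medians of 5.28 in cTfh and 0.29 between stimulated libraries. The mean of per-cell CPM gave cytokines 5.49 (Tcm) and 5.29 (cTfh) and a chemokine difference of 2.54. Thinned cells gave cytokines 5.25 and 4.78, chemokines 2.77 between stimulated libraries and 1.197 for the difference, and reversed GLCE (0.73 in Tcm, 0.49 between untreated libraries), whose counts came mostly from 1 barcode. Members with at least 50 counts gave cytokines 6.11 and 5.44, chemokines 7.34 and 6.95, Tfh genes 1.24 and activation receptors -0.012, a reversal, between untreated libraries; fewer genes enter these medians, and named genes got no value. Cells with 1000 to 3000 UMIs gave cytokines 5.82 and 4.81 and chemokines 4.52 and 1.78. Without the highest barcode of each gene, Tcm cytokines had 3.90, and between stimulated libraries cytokines had 0.73, chemokines 5.53 and Th17 genes 0.026, a reversal.

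From at least 2 UMIs, IL2 was found in 86.2% and 82.7% and IFNG in 5.83% and 45.0% of stimulated Tcm and cTfh cells. For the tumour, T or NK cell-like and macrophage or monocyte-like shares were 14.0% and 36.1% without Scrublet calls, 17.6% and 32.9% with 10 components, 0.0% and 18.8% with 1000 variable genes (71.1% unnamed), and 0.0% and 52.1% at resolution 0.2 (39.6% fibroblast-like, 0.0% unnamed). Scrublet called 0 cells in stimulated cTfh and 1 in the mix, so leaving out its calls says nothing about these libraries. The lowest median, 1250.5 UMIs per cell in untreated cTfh, limits shares of cells for genes of low level.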

Other observations

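Tests of CD8 T cells, of NK cells, of deeper cells and of dividing cells were chosen after the results were seen.

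CCL4 UMIs were present in 266 of 1256 stimulated cTfh cells, at least 2 of them in 113 cells, and in 4.58% of low-count barcodes. In these 266 cells CCL3 was 48.7-fold, XCL1 9.67-fold, GZMK 7.90-fold, NKG7 6.25-fold, EOMES 4.605-fold, CCL5 4.54-fold, CST7 1.95-fold, IFNG 1.93-fold and ZEB2 1.88-fold higher than in the other cells. GZMB, a cytotoxic gene, had a ratio of 0.990, and of 10.7 (5.36 to 23.2) without 1 barcode that held 109 of its 158 counts and 0 CCL4 UMIs. GZMA had 15 counts in cells with a CCL4 UMI and 0 in the others. Ratios were 0.9997 for IL2 and 1.01 for CD3D. Tfh genes were divided, with ratios of 0.781 for CXCR5, 0.832 for ICOS, 0.993 for TIGIT and 1.01 for IL21. MAF had a ratio of 1.43 (1.06 to 1.93) and PDCD1 of 1.45 (0.931 to 2.225). IL13 was found in 16 of 40 cells with an IL4 UMI and 21 of 1216 without.

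For the chemokine cells, deeper cells are argued against by thinned cells, where CCL5 was found in 28.2% of 117 cells with a CCL4 UMI and 4.29% of 676 without, a ratio of 6.58. NK cells would lack CD3D, whose ratio was 1.07 (0.871 to 1.30) in the 66 cells with at least 5 CCL4 UMIs. This argues against NK cells as the bulk of those cells, although TRAC fell to 0.659 (0.507 to 0.844). Of the NK genes, TYROBP, KLRF1 and FCGR3A had 0 counts in any cell. SPON2 had 2 counts, both in cells with a CCL4 UMI, and NCAM1 and GNLY each had 1 there and 1 in the others. KLRC1 had 3 counts and KLRD1 1, all in cells without CCL4. Counts this low decide little. CD8 T cells would carry less CD40LG, whose CPM ratio was 0.973 (0.922 to 1.03) in cells with a CCL4 UMI but 0.573 (0.510 to 0.642) in those 66, where TRAC and IL2 (0.774) fell too. CD8A had 0 counts in cells with a CCL4 UMI, but CD4 had only 5 there and 10 in all cells of this library, so 0 counts of such a receptor decide little, and CD8 T cells and a subset of helper T cells cannot be told apart. The 57 cells with both CCL4 and CCL5 had a median of 1932 UMIs against 1518, a ratio of 1.27 that lies between the bounds set for doublets and for single cells, so doublets stay open too.

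UBE2C, a gene of mitotic exit, was low in K562-like cells, at 2.73 CPM against 414 in HEK293-like and 287 in HUVEC-like cells. It was singled out after its values were seen. Fewer dividing cells are argued against, since the other 17 proliferation genes had a median ratio of 1.64 over the mean of the other classes (lowest 0.851). No other explanation was tested.

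Within the macrophage or monocyte-like cells of the tumour, a cluster of 38 cells was led by the interferon-induced genes Mx2, Mx1 and Ifit2, and a cluster of 26 cells by the mitotic genes Dlgap5, Bub1 and Aspm.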
